A study of Pinus pinaster with 6 samples.

How the data were processed

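Two-colour cDNA microarrays measured the ratio between crown and base developing xylem RNA in 3 pine trees, with 2 technical repeats per tree. Per the labels' protocols, total RNA was amplified and the amplified RNA was coupled to the dyes through amino allyl groups. The series text places both technical repeats on the same array, so they share a hybridisation and measure spotting and scanning error only. The deposited table holds 1 log2 ratio per probe and column, already normalised by the authors. R 2.7.1 and limma 2.14.5 are named in the submitters' processing notes without their role. The background correction, the normalisation method, the log base and the numerator of the ratio are not given in the sources used here. The values were taken as log2, the scale limma uses, and every fold in the text depends on that. The column medians lie near 0, as after centring, so a shift common to all probes cannot be seen in these values.

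The direction of the columns was examined before testing. The rule set before the data were examined was to turn the columns by the dyes if tree 1 correlated negatively with trees 2 and 3, and to leave them as deposited if the correlation was positive. It was positive in each pair, so no column was turned. In the 2 columns of tree 1, 98.9% and 99.0% of the values were written with more than 6 significant digits, and in the 4 columns of trees 2 and 3 no value was. The origin of this difference in format is not recorded.

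The repeats of a tree were averaged, and the 3 tree means of each probe were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over 3448 probes and a threshold of 0.05. Crown and base of 1 tree share an array, so the pairing by tree lies within the ratio. No probe was filtered out, since none had a missing value. The median standard error of a mean ratio was 0.10 on the log2 scale. The test was checked on 5 simulated tables of 3448 probes, 200 of them changed. Noise was drawn with each probe's own SD over the 3 trees. The test recovered 57.2% of changes of 0.5, 86.2% of changes of 1 and 98.7% of changes of 2 on the log2 scale. Of its calls, 5.07% were false. The simulated trees had independent noise, and the changed probes were picked at random. Each SD came from 3 values and was used as the true one, so the simulated SDs also carry the error of that estimate. In the data, trees 2 and 3 were more alike than either was to tree 1. The simulated shares therefore need not hold for the calls reported below. Plate counts were compared by permutation in R, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

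The rule for naming probes, fixed before the data were examined, was 2 codes per direction with the largest mean change among called probes of one sign in all trees, since the sources used here do not pair the codes with genes. For the same reason, 18 gene lists fixed in advance (wall synthesis, hormones, stress, translation, other tissues) could not be matched to any probe, and no list was tested. The alternatives set in advance were the tree as a random block, each repeat alone, a dye term, the opposite sign of tree 1, each tree left out, median centring, a common scale, 2 filters on missing values, and a robust variance estimate. A further 4 alternatives were chosen after seeing the data: leaving out the 16 probes, centring each plate, centring each 4 by 4 group of positions, and correlating trees within probes split by their ratio in the tree left out of the pair. Reading the codes as plates and wells is an interpretation of their form, and the layout of the slide is not given in the sources used here.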

Results

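Gene expression was compared between developing secondary xylem of the crown and of the trunk base in maritime pine (Pinus pinaster). Developing xylem is the layer of young wood cells scraped off beneath the bark. Crown material came from the youngest internodes and base material from the lowest part of the trunk. Crown and base RNA of the same tree were labelled with different dyes and hybridised together on a cDNA microarray. Each value is therefore a log ratio of the 2 tissues within 1 tree. There were 3 trees, aged 29, 31 and 28 years, and 2 technical repeats per tree, which gave 6 columns of ratios. Trees 1 and 2 were harvested in 2005 and tree 3 in 2007. In tree 1 the crown RNA carried Cy5 and the base RNA Cy3, and in trees 2 and 3 the dyes were the other way round. The trees are the biological replicates (n = 3), and the repeats of a tree were averaged.

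All 3448 probes had a value in all 6 columns. The column medians lay between -0.0142 and 0.00318 on the log2 scale, and the SD of the ratios lay between 0.353 and 0.415. Probe intensities were not analysed here, so the precision is limited by the number of trees, and no level above background can be given. The probes carry position codes only, and their gene names are not given in the sources used here. The comparison is therefore reported for probes and for groups of probe positions, not for genes.

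The sign of a ratio can be compared between trees but not assigned to a tissue. As deposited, the ratios of tree 1 correlated positively with those of trees 2 and 3 although the dyes were opposite, so by the rule set in advance the columns were taken as already turned to a common tissue order. All sample titles name the crown first, which would make a positive ratio a higher level in the crown. If instead the columns of trees 2 and 3 are red over green (Cy5 over Cy3), the ratio that limma forms, a positive ratio is a higher level in the base. "Positive" and "negative" below are the deposited signs. If the columns were not turned at all, the signal shared by the 3 trees would follow the dye, not the tissue. A common tissue order would then need the opposite sign for tree 1. That fit called 0 probes by limma (adjusted p under 0.05), with 229 at an unadjusted p under 0.05. In that fit the shared signal counts as spread between the trees and also enters the mean. Its 0 calls therefore do not show that tissue differences are absent. Unless the columns were turned before deposit, the counts below are not counts of tissue differences.

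The first question was how far the 3 trees gave the same ratio for a probe. Across probes, the tree means of trees 2 and 3 had a Pearson correlation of 0.78 and a Spearman correlation of 0.74. Tree 1 correlated with tree 2 at a Pearson r of 0.61 and a Spearman rho of 0.28, and with tree 3 at 0.67 and 0.42. These correlations run across probes, which are not independent replicates. The agreement of trees 1 and 2 was higher among the probes with large ratios in tree 3. The tree left out correlates with both trees of a pair. Each split by it therefore lowers r among the small ratios and raises it among the large ones, in part by construction. Among the 2949 probes with a ratio under 0.5 in size in tree 3, trees 1 and 2 correlated at a Pearson r of 0.18 and a Spearman rho of 0.0266, and among the other 499 probes at 0.86 and 0.77. Split by tree 2 in the same way, trees 1 and 3 still correlated among the 3116 probes under 0.5, at an r of 0.43 and a rho of 0.28, and at 0.87 and 0.85 among the rest. Split by tree 1, trees 2 and 3 correlated at an r of 0.69 and a rho of 0.70 among the 2969 probes under 0.5, and at 0.84 and 0.84 among the rest. Among the 3092 probes with a mean under 0.5 in size, a selection on the compared values themselves that lowers r, it was 0.095 for trees 1 and 2, 0.28 for trees 1 and 3 and 0.62 for trees 2 and 3. Without the 16 probes of high ratio described below, the 3 values of r over all probes were 0.54, 0.64 and 0.77. The technical repeats of 1 tree correlated at 0.95 in tree 1, 0.94 in tree 2 and 0.92 in tree 3. The median SD of a probe was 0.158 between trees and 0.0559 between repeats, and trees varied more than repeats for 86.0% of the probes. The spread between trees also holds labelling, hybridisation, dye orientation and harvest year, so it is not a measure of biological variation alone. The same sign was found in all 3 trees for 1580 of 3448 probes, or 45.8%, where unrelated signs would give 25%. The resemblance of trees 2 and 3 alone raises this share above 25%, so the excess is not a measure of agreement with tree 1. The rule for the columns also keeps the sign at which tree 1 correlates positively with trees 2 and 3. The positive sign of those correlations was therefore set by the rule, while their size was not.

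**Figure D1:**
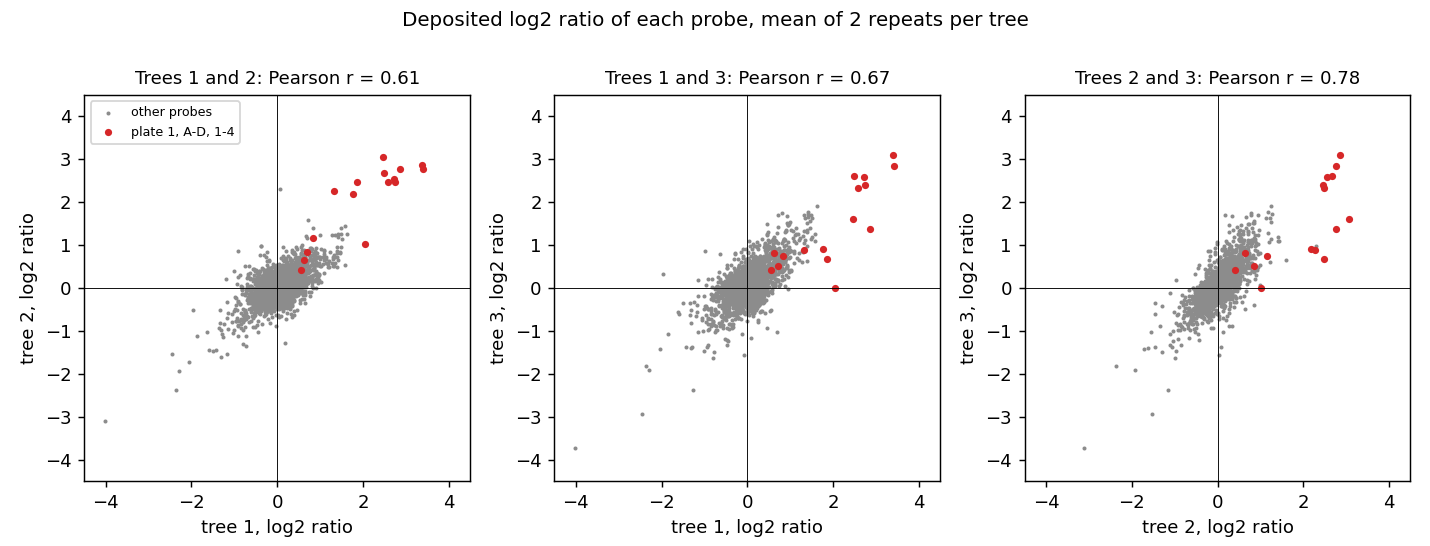
Deposited log2 ratio of each of 3448 probes in 1 tree (x axis) against another (y axis), each the mean of 2 technical repeats, for the 3 pairs of trees. Trees 2 and 3 lie closest to a line (r = 0.78), and the 16 probes of plate 1, rows A to D and columns 1 to 4 (red) are the most positive group in each panel.

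The main comparison asked which probes had different levels in crown and base xylem. With the deposited signs, 532 probes (15.4%) passed an adjusted p under 0.05 in limma, 367 with a positive and 165 with a negative ratio. All 532 had the same sign in the 3 trees, which a test of 3 values against 0 largely selects for. The median size of a called change was 0.58 on the log2 scale, which is 1.49-fold, and the smallest was 0.32. A change of at least 2-fold was called for 65 probes, 45 positive and 20 negative, and a change of at least 4-fold for 8 positive and 4 negative probes. A further 2 probes had a mean change of at least 2-fold and did not pass. The number with an unadjusted p under 0.05 was 914. Without tree 3, in the 2 trees of 2005, 348 probes were called, 233 of them positive. Of the 348, 325 were among the 532. Without tree 2, 504 probes were called, 344 of them positive. In the 2 trees with the same dye orientation, trees 2 and 3, 584 probes were called, 362 positive and 222 negative. The p-values of these fits on 2 trees differed widely in scale. For the probe Q1B1 the adjusted p was 1.78e-69 without tree 3 and 0.000467 without tree 1 (limma). The 3 counts therefore cannot be compared, and the lower count without tree 3 cannot be credited to that tree. The year 2007 and the swapped dye orientation each held 1 tree, so neither gives a count by itself. A model with a dye term, which sets tree 1 alone against the other trees with 1 residual degree of freedom, called 658 probes for the shared ratio in limma.

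**Figure D2:**
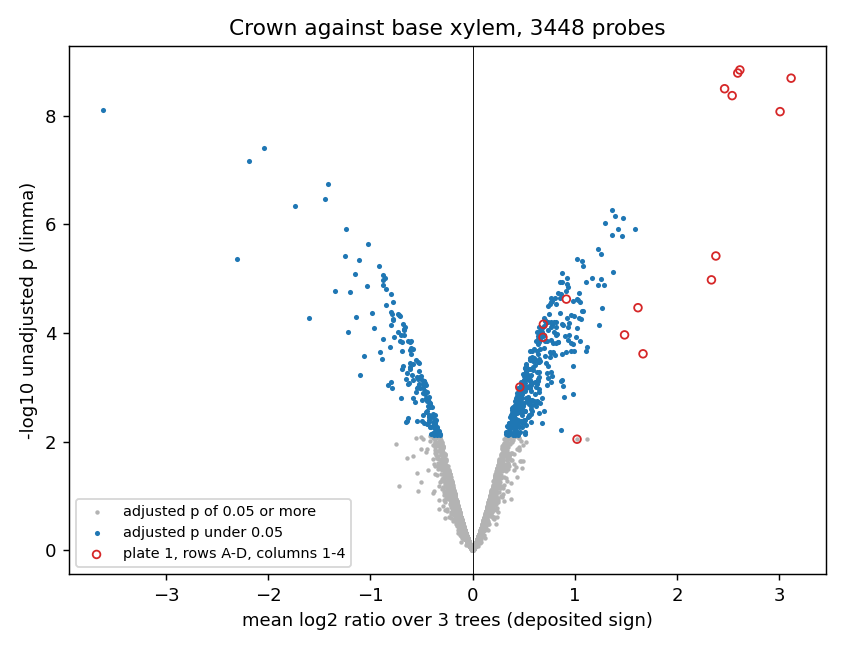
Mean log2 ratio of each probe over 3 trees (x axis, deposited sign) against the −log10 of its unadjusted limma p (y axis). Blue points are probes with an adjusted p under 0.05, and red circles mark the 16 probes of plate 1, rows A to D and columns 1 to 4, of which 15 were called.

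By the naming rule, 2 probes per direction are described. The most negative probe, Q7H1, had a mean log2 ratio of -3.61 ± 0.46 (SD, n = 3 trees), a 12.2-fold difference with a 95% confidence interval of 9.50 to 15.7 (adjusted p = 4.12e-06, limma). Its tree means were -4.01, -3.10 and -3.72. The second, Q6I16, had a mean of -2.31 ± 0.72 (SD, n = 3), or 4.96-fold (3.49 to 7.05; adjusted p = 0.000538, limma), and its tree means spread from -1.53 in tree 2 to -2.95 in tree 3. The 2 most positive probes were Q1B1, at 3.12 ± 0.26 (SD, n = 3) or 8.68-fold (7.21 to 10.4; adjusted p = 2.33e-06, limma), and Q1C4, at 3.01 ± 0.35 (SD, n = 3) or 8.05-fold (6.51 to 9.95; adjusted p = 4.12e-06, limma). Both belong to the group of 16 adjoining positions described next. When each 4 by 4 group of positions was centred on its own median, their means were 1.16 and 1.05 and neither passed (adjusted p = 0.0610 and 0.0611, limma). That centring subtracts a median these 2 probes and their neighbours set themselves, so the loss follows from its construction. With the opposite sign for tree 1, the 4 probes had means of -0.94, -0.68, 0.86 and 0.74 in the order described, with adjusted p from 0.884 to 0.903 in limma.

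The large positive ratios were concentrated in 1 small area of the probe positions. The position codes have the form of 9 plates of 16 rows (A to P) and 24 columns, and 3448 of the 3456 possible positions were present. In plate 1, rows A to D and columns 1 to 4, all 16 probes had positive means, with a median of 2.00 (4.01-fold) and a range from 0.46 to 3.12. The test called 15 of the 16, and 15 had one sign in all 3 trees. Their median was 2.26 in tree 1, 2.47 in tree 2 and 1.15 in tree 3. The group held 11 of the 12 most positive probes and all 8 called positive changes of at least 4-fold, and the highest mean among the other 3432 probes was 1.59. A mean change of at least 2-fold was found for 12 of these 16 probes and 55 of the other 3432 (Fisher's exact test over probes, two-sided, p = 1.78e-18; the area was chosen after its values were seen). The positions form 216 such 4 by 4 groups, and in the others the median ratio lay between -0.16 and 0.36. Without the 16 probes, 520 probes were called, 353 positive and 167 negative, and 54 changed at least 2-fold, 34 of them positive.

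**Figure D3:**
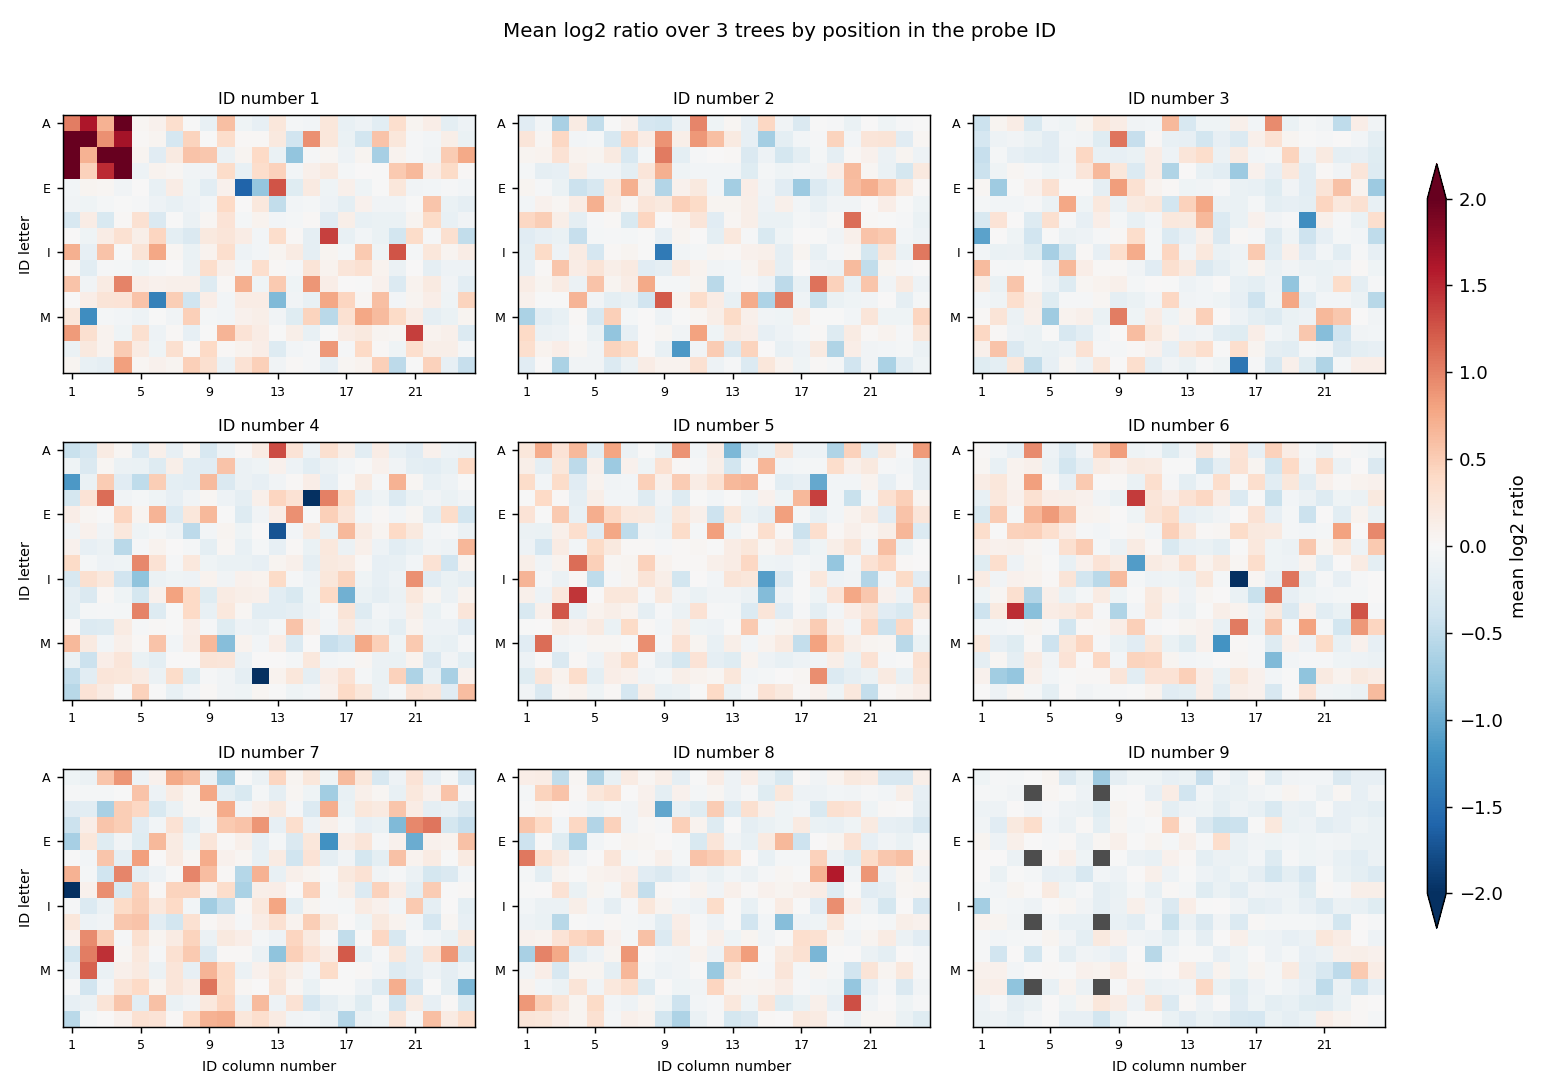
Mean log2 ratio over 3 trees by the position in the probe code, with 1 panel per plate number, rows A to P downwards and columns 1 to 24 across (colour scale limited to −2 to 2, dark grey for the 8 absent positions). The 16 positions at the upper left of plate 1 stand out with a median of 2.00, and plate 9 is the palest panel.

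Positive calls were unevenly spread over the plates. They made up 18.5% of plate 7 (71 of 384) and 17.7% of plate 1 (68 of 384), against 1.06% of plate 9 (4 of 376) and 7.55% to 11.98% of the other plates. A permutation test of the positive calls over the 9 plates gave p = 1e-05, the smallest that 100000 permutations can give (adjusted 2e-05 over 2 tests). The permutation treats probes of the same 3 trees as independent units, so its p does not measure replication over trees. The plate comparison was not among those set in advance. Of the 68 positive calls of plate 1, 15 belonged to the 16 positions above. Without these positions, plate 1 held 53 of 368 (14.4%), and the permutation test again gave p = 1e-05. Negative calls ranged from 3.19% of plate 9 to 6.51% of plate 3, and the same permutation test gave p = 0.481. Plate 9 also had the narrowest mean ratios, with a median absolute deviation of 0.115 against 0.153 to 0.267 in plates 1 to 8.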

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

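The count of 532 called probes (367 positive, 165 negative, 65 of at least 2-fold) depended most on the sign of tree 1: with the opposite sign, limma called 0 probes, 0 positive, 0 negative and 0 of at least 2-fold, and 229 probes had an unadjusted p under 0.05. Leaving out each tree gave 348 to 584 calls, 233 to 362 of them positive, with the lowest values without tree 3. The p-values of these fits on 2 trees differed too widely in scale for their counts to be compared. The model with a dye term fits tree 1 exactly, so its error rests on trees 2 and 3 alone, with 1 residual degree of freedom. Its count, given above, is therefore no check of how stable the calls are. The other alternatives kept every count within 1.5 times. The tree as a random block gave 569 calls, repeat 1 alone 465, repeat 2 alone 481, median centring 512, a common scale 534 and a robust variance 533. Both filters on missing values removed no probe and so tested nothing. Of the alternatives chosen after seeing the data, centring plates gave 487 calls and centring 4 by 4 groups of positions 389, of which 363 were among the 532. The share of positive calls stayed between 62.0% and 69.5% wherever probes were called. Median centring or a single repeat left r of trees 1 and 2 at 0.57 to 0.61, of trees 1 and 3 at 0.63 to 0.67 and of trees 2 and 3 at 0.75 to 0.78, and the share of probes with one sign at 44.7% to 45.9%. Without the 16 probes, chosen after seeing the data, these were 0.54, 0.64, 0.77 and 45.6%. On a common scale the median SD was 0.157 between trees and 0.0563 between repeats. The gene list tests and the averaging of probes of one gene could not be run because gene names are not given in the sources used here. With 3 trees and no intensities, dim and bright probes could not be weighed differently.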

Other observations

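The tests here were chosen after the results were seen, except the dye term and the opposite sign of tree 1, which were planned. The highest positive ratios sat in 16 adjoining position codes. The 8 positions absent from the table all fall on plate 9 at the same place within a 4 by 4 grid of wells. Print tips arranged 4 by 4 would take up adjoining wells together, and the 16 positions would then hold the first spot of each of the 16 tips. The medians of the 16 supposed tips were within 0.0397 of 0 in each tree. The SD of these medians was lower than in all 1000 random groupings of the probes in tree 3, and as low in 6 of 1000 in tree 2 and 86 of 1000 in tree 1.

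For these 16 positions, the SD of the mean ratios was 0.89, which was 6.82 times the median SD between repeats there. That argues against a single probe printed in every well only if repeats hold the whole error between positions. Differences between the supposed tips, or between places on the slide, may not be part of the SD between repeats, so this explanation stays open. A gradient along the print order that reached past the first spots is argued against by the 32 probes of the adjoining groups, whose median was 0.0210 and of which 0 changed 2-fold or more. Marker spots with a dye of their own remain a possible explanation: 15 of the 16 kept one sign in all 3 trees, which such spots would do only if the columns were not turned, and that is not recorded. A set of related transcripts, such as clones of one gene family or genes chosen for this comparison, may also have been placed first on the plate, and this was not tested.

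Trees 2 and 3 were more alike than either was to tree 1. A shared harvest year as the source of the resemblance is argued against by the labels, since trees 2 and 3 were harvested in different years. Trees 1 and 2 share the year 2005, and r of trees 1 and 2 minus r of trees 2 and 3 was -0.172 (95% bootstrap interval over probes -0.211 to -0.136). Trees 2 and 3 share the dye orientation, and their r was higher than the mean r with tree 1 by 0.141 (0.113 to 0.171). Both differences of r restate the pattern and add no test of their own, so only the years in the labels bear on harvest year, and dye orientation was not tested. Tree 1 alone had the swapped dyes, so dye and the individual tree cannot be told apart for these 3 trees. In the model with a dye term, limma called 0 probes for that term, with 668 at an unadjusted p under 0.05. That term sets 1 tree against 2 with 1 residual degree of freedom, so it excludes no dye effect. In columns that were not turned, the same term would hold the tissue difference in place of the dye.

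The ratios shared by the 3 trees may come from the tissues or from the dyes, depending on whether the columns were turned before deposit. As deposited 532 probes were called. Of the 4 sign patterns of 3 trees, 1 gave as many calls, the deposited one, and the highest of the others gave 0. So few patterns cannot give a share under 0.05, and the rule for the columns keeps the sign at which tree 1 correlates positively with the others. A dye effect in columns that were not turned also predicts the loss of calls to 0 with the opposite sign of tree 1, so it cannot be told apart from a tissue effect in turned columns. The original scanner files, or gene names for a few probes of known tissue preference, would help to tell them apart.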
